A study of Mus musculus with 6 samples.

How the data were processed

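Gene expression was measured by mRNA sequencing in pancreas dissected from mouse embryos of the NMRI strain at E13.5. Per the labels, 3 control pools from wildtype embryos were set against 3 mutant pools from embryos the labels call Prox1-nullyzygous, with the genotype written Prox1 GFPCre/D. Prox1 is a homeobox transcription factor gene. Each pool held 5 to 6 pancreata of the same genotype, and 1 library was made from each pool with an Illumina TruSeq kit from 2 to 3 µg of total RNA. The labels' protocol names Trizol for RNA extraction, while the design text of the series names a column kit, so the extraction method is not settled here. The labels do not say that pools with equal replicate numbers shared a litter or a day, and they name no batch.

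The deposited files give whole-number read counts per gene for 23337 gene symbols in each library, and the authors' values were not normalized. Per the submitters' processing notes, the tools named were cutadapt 1.13, STAR, HTSeq 0.6.1p1 and DESeq2, with genome build mm10. The notes as used here give no role or order for these tools. The STAR version, the gene annotation, the strand setting and the treatment of reads that map to several places are not given in the sources used here. Near-identical gene copies can lose or exchange reads under such counting, so values of trypsinogen genes, Serpina1 genes and the insulin gene pair are uncertain, and Hba-a1, Hba-a2, Amy2a5, Eno1 and Ccl21a were listed at 0 in every library. Without a stated strand setting, reads of overlapping genes on opposite strands cannot be told apart.

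The total count was 16573638, 16325177 and 16954513 reads in control pools 1 to 3 and 16060424, 17152013 and 17633867 reads in mutant pools 1 to 3. At this depth, 1 CPM, the unit of counts scaled to library size, stands for 15.9 to 17.5 reads, so genes below about 1 CPM carry large counting error. CPM values in the text are counts divided by the library's total count scaled by its TMM factor, and are given as mean ± SD over 3 pools unless stated otherwise. Positions are from GENCODE release M21 on GRCm38, the assembly also called mm10. Symbols were matched directly or through older synonyms, and 22826 of the 23337 symbols (97.8%) received a position.

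Mutant and control libraries were compared with edgeR 4.0.16 in R 4.3.3. Genes were kept by filterByExpr with a minimum count of 10, libraries were scaled by TMM, and the quasi-likelihood F test was fitted with genotype as the only term. Adjusted p is the Benjamini-Hochberg value over the 14687 genes tested, and a gene was called changed at an adjusted p under 0.05. Standard errors of log2 fold changes were the size of the coefficient divided by the square root of F, and 95% intervals are normal intervals from them. Log2 fold changes are mutant minus control, so negative values are lower in mutants.

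A family of 23 gene lists was tested with camera from limma 3.58.1, with a preset correlation of 0.01 between genes and Benjamini-Hochberg adjustment over the lists. A list of sex-linked genes served only to describe each pool. Of the list members, 447 were found under the same symbol and 10 under an older symbol, and 4 were not found. Camera with an estimated correlation and fry were run as alternatives. The groups, the test, the lists, the alternatives except those named as added later and the rule for named genes were fixed before the data were examined. The rule named Prox1, the 8 called genes with the highest and the 8 with the lowest log2 fold change among those with an average log2 CPM of at least 1 and no overlap between groups, up to 3 called members of each list with the smallest adjusted p, and a fixed set that included Neurog3, Ins1, Ins2, Gcg, Cpa1, Ptf1a, Pdx1, Sox9, Nkx6-1, Spp1, Cldn2, Flt4, Lyve1, Pecam1 and Col1a1. Gene models without a standing name were left out of the first part of the rule. Other list members appear as examples of their list and were chosen after their values were seen. Results for some genes that the rule or the lists name are not reported here.

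The alternatives were DESeq2 size factors, upper-quartile scaling and total-count scaling in edgeR, no filter on low counts, a filter of at least 1 CPM in 3 libraries, the DESeq2 1.42.0 Wald test, limma voom, edgeR with robust estimation, removal of the erythroid list genes, the replicate number as a block, and leaving out each library in turn. A fit without the libraries that had almost no Xist counts was added after the data had been seen. The edgeR test was tested on simulated counts for the comparison of mutant against control over 14595 genes, and it recovered 51.5% of genes changed by 0.5 log2, 87.7% of those changed by 1 log2 and 97% of those changed by 2 log2. In the same simulation 15 unchanged genes were called and 0 changed genes had the wrong sign. The true calls were 35 of 68, 57 of 65 and 64 of 66 genes changed by 0.5, 1 and 2 log2. The 15 false calls were thus a larger share of all calls than the threshold for adjusted p allows on average. A single simulation cannot show whether this excess would recur. In simulated data for 14687 genes without any change, 1 gene and 1 list were called. The simulated genes were drawn independently, while the estimated correlation within the real lists reached 0.767 for blood endothelium. That run therefore cannot show how often camera calls a correlated list that has no change. With 51.5% recovered at 0.5 log2, differences of 0.5 log2 or less can go uncalled at this sample size. Python 3.11.15 and matplotlib 3.10.9 were used for tables and plots.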

Results

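RNA from mouse pancreas at E13.5, in the middle of gestation, was sequenced to compare organs labelled as Prox1 mutant with organs labelled as wildtype. The data comprised 6 libraries, 3 control and 3 mutant, each made from a separate pool of 5 to 6 pancreata. Total counts lay between 16060424 and 17633867 reads per library, and between 17332 and 17473 genes had at least 1 count. The first principal component held 52.4% of the variance between libraries and separated the control from the mutant libraries, and the second held 17.1%. The spread between pools of a group was small, with a biological coefficient of variation of 8.2% over all genes. Sex-linked transcripts differed between pools within each group. Xist, the RNA that silences the inactive X chromosome, stood at 0.526 CPM in control pool 3 and 0.126 CPM in mutant pool 1, against 2015 to 2814 CPM in the other pools. The Y-linked gene Ddx3y was highest in those same pools, at 110.7 CPM in control pool 3 and 126.9 CPM in mutant pool 1.

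Prox1, the targeted gene, lies on chromosome 1 from 190118035 to 190170714 on the minus strand (GRCm38, ENSMUSG00000010175.13). It encodes a homeodomain transcription factor of pancreatic progenitors, endocrine cells, lymphatic endothelium and hepatocytes. Its read counts were 1764, 1687 and 1824 in the control pools and 1330, 1774 and 1602 in the mutant pools. These counts corresponded to 104.9 ± 1.96 CPM (SD, n = 3) in controls and 93.3 ± 10.5 CPM (SD, n = 3) in mutants. The log2 fold change of -0.17 (SE 0.074) was not called by edgeR (adjusted p = 0.235), and the groups overlapped. Of the 8390 bases of exon annotated for the gene, 2211 are coding and 5188 (61.8%) are 3′ untranslated region. The labels do not say which part of the locus the mutant alleles lack, so the gene count does not check the genotype labels.

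The comparison of mutant with control pools asked how the transcriptome of the embryonic pancreas differed between the labelled genotypes, in a series titled for Prox1 deficiency. Genes of endocrine progenitors and of hormone-producing cells were lower in mutants, as was a group of secreted plasma protein genes listed as hepatocyte markers. A subset of acinar genes was higher in mutants by up to 59.3-fold, among them the protease gene Ctrl and the zymogen granule gene Gp2. Both stood below 1 CPM in controls, so the size of their folds is imprecise. Erythroid regulator genes and several extracellular matrix genes were also higher, while genes of the S to M phases of the cell cycle showed no called difference. Each library came from pooled pancreata of mixed cell types. A changed share of a cell type therefore cannot be told apart from a change within its cells. In all, edgeR called 1167 of 14687 genes (7.9%), of which 539 were higher and 628 lower in mutants. The split was 463 higher and 717 lower with total-count scaling, and 676 higher and 628 lower with DESeq2. A change of at least 1 log2 was seen for 130 of the higher and 202 of the lower genes. Among all 14687 genes tested, called or not, 3882 (26.4%) had no overlap between the 3 control and the 3 mutant values, where chance gives 10% for groups of this size. The 1167 called genes were all among them.

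The number of calls depended on single pools. The total was 629 without control pool 1, 767 without mutant pool 1, 648 without mutant pool 2 and 776 without mutant pool 3. It was 798 without control pool 3 and rose to 1421 without control pool 2. Genes called higher numbered 282 without control pool 1, 355 without mutant pool 1 and 290 without mutant pool 2. Genes called lower numbered 347 without control pool 1, 416 without control pool 3, 412 without mutant pool 1, 358 without mutant pool 2 and 343 without mutant pool 3. Genes lower by at least 1 log2 numbered 126 without control pool 3. Without both pools that had almost no Xist counts, 665 genes were called, 315 higher and 350 lower. Of the 23 gene lists, camera called 7 higher and 6 lower, and none of these calls held with an estimated correlation between genes. The lists called higher numbered 4 without control pool 3 and 4 without mutant pool 1.

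**Figure D1:**
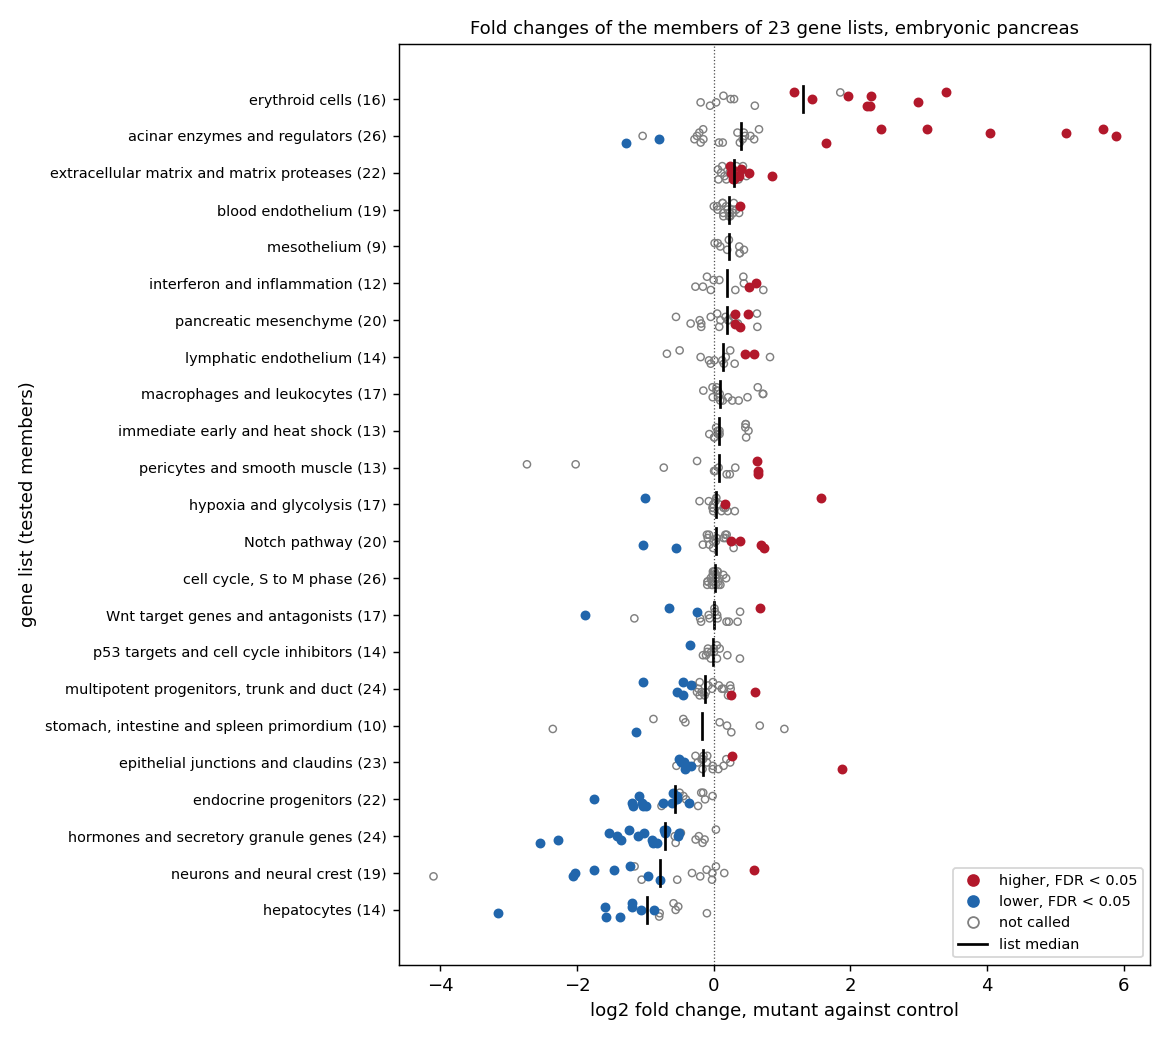
Log2 fold change (mutant minus control) of each tested member of the 23 gene lists, with 1 horizontal strip per list. Red points were called higher and blue points lower by edgeR at an adjusted p under 0.05, open points were not called, and the black bar is the list median, which runs from -0.97 for hepatocyte genes to 1.30 for erythroid genes.

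Endocrine progenitor genes were lower as a group in mutants. Of 22 tested members, 13 were called lower, 0 higher and 9 not called, and 17 were called lower when adjusted over the list alone. The list median was -0.57, and camera called the list lower (adjusted p = 2.55e-22; adjusted p = 0.161 with an estimated correlation). Neurog3, the transcription factor that commits progenitors to the endocrine lineage (chromosome 10, 62133090 to 62134763), fell from 139.4 ± 25.4 CPM in controls to 65.7 ± 3.37 CPM in mutants, a 2.12-fold decrease. Its log2 fold change was -1.09 (SE 0.118, adjusted p = 0.00105 by edgeR). Btbd17, a gene marking Neurog3-positive cells, changed by -1.19 (SE 0.128). Pax4, Pax6, Myt1, Insm1, Nkx2-2, Rfx6 and Neurod1 were also called lower. Isl1 at -0.13 (SE 0.068) and Runx1t1 at -0.02 (SE 0.049) were not called.

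Hormone and secretory granule genes fell along with them. Of 24 tested members, 16 were called lower, 0 higher and 8 not called, and 17 were lower when adjusted over the list alone. The median was -0.72, and camera called the list lower (adjusted p = 2.83e-23; adjusted p = 0.0832 with an estimated correlation). Gcg, encoding proglucagon, was the most abundant hormone transcript and dropped from 1449 ± 175 to 879.4 ± 23.5 CPM, a log2 fold change of -0.72 (SE 0.08, adjusted p = 0.00117 by edgeR). Iapp, encoding the beta cell peptide amylin, changed by -2.29 (SE 0.202), from 21.6 ± 4.29 to 4.42 ± 1.18 CPM. Pyy, encoding peptide YY, changed by -1.35 (SE 0.145) and the prohormone convertase gene Pcsk2 by -1.02 (SE 0.089). The insulin genes were expressed at low levels and are close copies of each other. Ins1 changed by -1.41 (SE 0.275, adjusted p = 0.0152 by edgeR) and Ins2 by -1.53 (SE 0.353, adjusted p = 0.0316 by edgeR). The Ins1 call was lost without mutant pool 2 (edgeR adjusted p = 0.0533) and without mutant pool 3 (0.0604). The Ins2 call was lost without control pool 1 (edgeR adjusted p = 0.0639), mutant pool 1 (0.058), mutant pool 2 (0.111) or mutant pool 3 (0.103), and with limma voom (0.0702). Sst, encoding somatostatin, stood at 0.771 ± 0.315 CPM in controls and 0.525 ± 0.312 CPM in mutants and was not called, and Chgb and Peg3 were not called either.

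Acinar genes moved in both directions. Of 26 tested members, 7 were called higher, 2 lower and 17 not called, and 8 were higher and 3 lower when adjusted over the list alone. The median was 0.40, and camera called the list higher (adjusted p = 1.45e-06; adjusted p = 0.400 with an estimated correlation). Ctrl, encoding a chymotrypsin-like protease, rose from 0.438 ± 0.0939 to 26.4 ± 11.3 CPM, a log2 fold change of 5.89 (SE 0.468, adjusted p = 0.000242 by edgeR). Gp2, the major glycoprotein of the zymogen granule membrane (chromosome 7, 119442537 to 119459285), rose from 0.297 ± 0.0969 to 15.8 ± 3.47 CPM, a log2 fold change of 5.70 (SE 0.28, adjusted p = 2.36e-05 by edgeR). Control pools 1 to 3 held only 9, 7 and 6 reads of Ctrl and 4, 4 and 7 reads of Gp2. The 95% interval of the Ctrl log2 fold change ran from 4.97 to 6.81. The carboxypeptidase gene Cpb1 rose by 3.12 (SE 0.414) and the pancreatic ribonuclease gene Rnase1 by 5.15 (SE 0.791), the latter from 0.0978 ± 0.122 CPM, a few reads per library. Among the trypsinogens, whose near-identical copies make single values uncertain, Prss1 rose by 4.04 (SE 0.634), Prss2 by 2.45 (SE 0.431) and Prss3, which is not on the list, by 4.13 (SE 0.619). Control pool 3 held 2.75 CPM of Prss1 and 2.63 CPM of Prss3, where the other control pools held at most 0.239 CPM of either. Robust estimation in edgeR left Prss1 (adjusted p = 0.0638) and Prss3 (adjusted p = 0.0532) uncalled. Bhlha15, a transcription factor of mature secretory cells, and the elastase gene Cela3b were called lower, by -0.80 (SE 0.19) and -1.29 (SE 0.319). The abundant enzyme gene Cpa1, at 1269 ± 343 CPM in controls and 1743 ± 292 CPM in mutants, was not called (log2 fold change 0.46, SE 0.191, adjusted p = 0.210 by edgeR). Ptf1a, the acinar lineage transcription factor, was not called at 0.08 (SE 0.14). Without control pool 3, 11 members were called higher, and the log2 fold changes became 6.33 for Prss1, 7.06 for Prss3, 6.65 for Rnase1 and 3.73 for Cpb1.

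**Figure D2:**
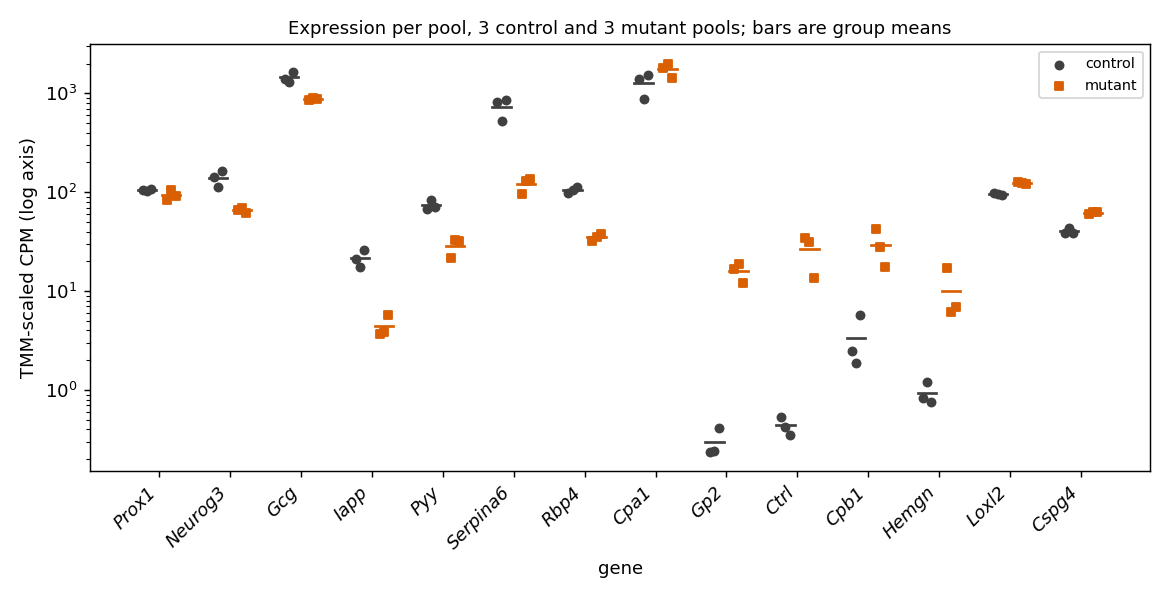
Expression in TMM-scaled CPM (log axis) of 14 genes in each of the 3 control and 3 mutant pools, where each point is a pool and each bar a group mean. Prox1 overlaps between groups, Neurog3, Gcg, Iapp, Pyy, Serpina6 and Rbp4 lie lower in all mutant pools, Gp2, Ctrl, Cpb1, Hemgn, Loxl2 and Cspg4 lie higher in all mutant pools, and Cpa1 overlaps.

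Genes listed as hepatocyte markers, most of which encode secreted plasma proteins, were lower in mutants. Of 14 tested members, 8 were called lower, 0 higher and 6 not called, and 10 were lower when adjusted over the list alone. The median was -0.97, and camera called the list lower (adjusted p = 9.67e-23; adjusted p = 0.0822 with an estimated correlation). Rbp4, encoding the plasma retinol carrier, fell from 105.6 ± 7.47 to 35.1 ± 3.18 CPM, a log2 fold change of -1.59 (SE 0.078, adjusted p = 2.36e-05 by edgeR). Ambp, encoding the precursor of alpha-1-microglobulin and bikunin, fell from 316.6 ± 40.5 to 151.7 ± 13 CPM. Afp, encoding alpha-fetoprotein, changed by -1.58 (SE 0.155), and Ttr, encoding the thyroxine carrier transthyretin, by -0.88 (SE 0.131). Alb, encoding albumin and the most abundant plasma protein, was scarce in both groups, at 3.79 ± 0.961 CPM in controls and 0.419 ± 0.181 CPM in mutants. Outside the list, Serpina6, encoding corticosteroid-binding globulin (chromosome 12, 103646630 to 103657212), fell from 731.5 ± 183 to 120.2 ± 21.7 CPM, a log2 fold change of -2.61 (SE 0.196, adjusted p = 0.00019 by edgeR). The close copies Serpina1c and Serpina1e changed by -2.83 (SE 0.416) and -2.97 (SE 0.51; -3.77 without mutant pool 2), and Tmprss6, encoding a membrane serine protease of hepatocytes, by -2.72 (SE 0.272). Cdhr1, encoding a cadherin-related protein, and Aqp4, encoding a water channel, completed the 8 genes with the lowest log2 fold change together with Iapp, at -3.10 (SE 0.197) and -2.56 (SE 0.273).

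Progenitor, trunk and duct genes shifted less. Of 24 tested members, 2 were called higher, 5 lower and 17 not called, and 2 were higher and 7 lower when adjusted over the list alone. The median was -0.12, and camera called the list lower (adjusted p = 0.0364; adjusted p = 0.400 with an estimated correlation). Dcdc2a, encoding a microtubule-binding protein, changed by -1.04 (SE 0.102), while the ductal keratin gene Krt19 rose by 0.61 (SE 0.061), from 32.7 ± 1.92 to 49.8 ± 0.638 CPM. The transcription factor genes Nkx6-1 and Hnf4a were called lower, at -0.45 (SE 0.108) and -0.44 (SE 0.086). By edgeR, the Nkx6-1 call was lost without control pool 3 (adjusted p = 0.0787), mutant pool 1 (0.116), mutant pool 2 (0.0529) or mutant pool 3 (0.113), and the Hnf4a call without mutant pool 1 (0.0527) or mutant pool 3 (0.0509). Pdx1 at -0.31 (SE 0.101), Sox9 at -0.25 (SE 0.072) and Spp1 at -0.23 (SE 0.088) were not called, and Sox9 was called with DESeq2 (adjusted p = 0.0178). Members called lower numbered 3 without control pool 1, 2 without control pool 3, 1 without mutant pool 1, 2 without mutant pool 2 and 1 without mutant pool 3. The list call was lost without control pool 3 (camera adjusted p = 0.137), mutant pool 1 (0.0963) or mutant pool 3 (0.0603), and without both pools that had almost no Xist counts (0.246).

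Among epithelial junction genes, 2 of 23 tested members were called higher, 5 lower and 16 not called, and 2 were higher and 7 lower when adjusted over the list alone. The median was -0.16, and camera called the list lower (adjusted p = 0.0355; adjusted p = 0.544 with an estimated correlation). Cldn2, encoding a pore-forming claudin, rose from 1.69 ± 0.149 to 6.22 ± 0.665 CPM, a log2 fold change of 1.87 (SE 0.172, adjusted p = 0.000504 by edgeR). Cldn3, encoding a sealing claudin, changed by -0.48 (SE 0.081) and Cdh1, encoding E-cadherin, by -0.42 (SE 0.074), from 626.9 ± 65.4 to 468.1 ± 22.3 CPM. Epcam at -0.18 (SE 0.095) was not called. Members called lower numbered 2 without control pool 1, 3 without control pool 3, 2 without mutant pool 1 and 2 without mutant pool 3. The list call was lost without control pool 3 (camera adjusted p = 0.196), mutant pool 1 (0.0963) or mutant pool 3 (0.0603), and without both pools that had almost no Xist counts (0.425).

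Several markers of neurons and neural crest were called lower in mutants. Of 19 tested members, 7 were called lower, 1 higher and 11 not called, and 9 were lower and 1 higher when adjusted over the list alone. The median was -0.79, and camera called the list lower (adjusted p = 1.83e-05; adjusted p = 0.345 with an estimated correlation). Ret, encoding the receptor for glial cell line-derived neurotrophic factor, changed by -0.79 (SE 0.118), from 45.2 ± 5.89 to 26.1 ± 3.61 CPM. Gfra1, encoding the co-receptor of Ret, rose by 0.59 (SE 0.085). The noradrenaline synthesis gene Dbh, not called, stood at 8.65 CPM in control pool 3 and at 1.04 CPM or less in the other pools. Without mutant pool 2, 4 members were called lower. Of 10 tested markers of stomach, intestine and spleen primordium, 1 was called lower and 9 were not called, and adjusted over the list alone 1 was higher and 2 lower. The lower gene, the transcription factor gene Onecut3, changed by -1.14 (SE 0.289), and it remained called only without control pool 3, with edgeR adjusted p between 0.0824 without control pool 2 and 0.128 without mutant pool 1 for the other pools left out. Sox2, a foregut transcription factor, stood at 5.73 CPM in control pool 2 and at 0.716 CPM or less elsewhere. DESeq2 called 3 members of the gut list lower and limma voom 0, and the list was not called (camera adjusted p = 0.569).

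Blood cell markers differed between the groups. Of 16 tested erythroid genes, 8 were called higher in mutants, 0 lower and 8 not called, and 9 were higher when adjusted over the list alone. The median was 1.30, and camera called the list higher (adjusted p = 5.71e-08; adjusted p = 0.353 with an estimated correlation). Hemgn, encoding a nuclear protein of haematopoietic cells, rose from 0.938 ± 0.246 to 10 ± 6.04 CPM, a log2 fold change of 3.40 (SE 0.456, adjusted p = 0.00282 by edgeR). Without mutant pool 1 the log2 fold change of Hemgn was 2.79. The erythroid spectrin gene Spnb1 rose by 1.17 (SE 0.191), from 11.2 ± 0.75 to 25.3 ± 7.66 CPM. Globin genes were not called, among them the abundant embryonic gene Hbb-y, at 1564 ± 427 CPM in controls and 1726 ± 392 CPM in mutants. Without control pool 1 the members called higher numbered 4, and without control pool 3 they numbered 5. Mpo, encoding the myeloperoxidase of neutrophil precursors, rose from 2.29 ± 0.155 to 27.7 ± 13.8 CPM, a log2 fold change of 3.59 (SE 0.36, adjusted p = 0.000687 by edgeR). Of 17 macrophage and leukocyte markers, 0 were called by edgeR, also when adjusted over the list alone, while 5 had an unadjusted value under 0.05 and 2 were called by DESeq2 and 0 by limma voom. The list was not called (camera adjusted p = 0.0605), but it was called higher with total-count scaling (0.0412), no filter on low counts (0.0449) and limma voom (0.0291). The replicate block also called it higher (camera adjusted p = 0.0171), with 3 members called. Without control pool 1 that list was called higher (camera adjusted p = 0.000815), as it was without mutant pool 3 (0.0104), and 1 member was called without control pool 1. Akr1cl, encoding an aldo-keto reductase (chromosome 1, 65012689 to 65032759), was the remaining gene among the 8 with the highest log2 fold change and rose from 10.1 ± 2.11 to 144.5 ± 19.9 CPM.

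Endothelial genes changed little. Of 14 tested lymphatic genes, 2 were called higher and 12 not called, and adjusted over the list alone 3 were higher and 2 lower. The list was not called (camera adjusted p = 0.256). Itga9, encoding an integrin subunit of lymphatic valves, rose by 0.59 (SE 0.082), and Pdpn, encoding podoplanin, by 0.45 (SE 0.091). The edgeR call of Pdpn was lost without control pool 1 (adjusted p = 0.0644), control pool 3 (0.0573), mutant pool 1 (0.0612) or mutant pool 2 (0.0767), which left 1 called member. Flt4, encoding the receptor for vascular endothelial growth factor C, was not called at 0.01 (SE 0.094), and its sign turned with total-count scaling. Lyve1, encoding a hyaluronan receptor, was not called at -0.50 (SE 0.157, adjusted p = 0.0991 by edgeR), and was called without control pool 2 (edgeR adjusted p = 0.0111) and with DESeq2 (adjusted p = 0.0227). Of 19 blood endothelial genes, 1 was called higher, 0 lower and 18 not called, and 1 was higher when adjusted over the list alone. The median was 0.23, and camera called the list higher (adjusted p = 0.00118; adjusted p = 0.539 with an estimated correlation). That call was lost without mutant pool 1 (camera adjusted p = 0.0696) and without both pools that had almost no Xist counts (0.425, with 0 members called). DESeq2 called 2 blood endothelial members. The member called by edgeR was Flt1, a receptor for vascular endothelial growth factor A, at 0.38 (SE 0.091). Its edgeR call was lost without control pool 1 (adjusted p = 0.0864), control pool 3 (0.114), mutant pool 1 (0.0812) or mutant pool 3 (0.0724). Pecam1 at 0.23 (SE 0.091) was not called.

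Of 20 tested pancreatic mesenchyme genes, 4 were called higher, 0 lower and 16 not called, and 9 were higher and 3 lower when adjusted over the list alone. The median was 0.19, and camera called the list higher (adjusted p = 0.0346; adjusted p = 0.400 with an estimated correlation). The list call was lost without control pool 3 (camera adjusted p = 0.14), without mutant pool 1 (0.0657) and without both pools that had almost no Xist counts (0.167). The collagen gene Col5a1 was called higher at 0.32 (SE 0.059) and lost its call without mutant pool 2 (edgeR adjusted p = 0.0664). Col1a1, at 1806 ± 116 CPM in controls and 2246 ± 149 CPM in mutants, was called higher at 0.31 (SE 0.066). Its edgeR call was lost without control pool 1 (adjusted p = 0.083), control pool 3 (0.059), mutant pool 1 (0.0612) or mutant pool 2 (0.104). Called mesenchyme members numbered 1 without control pool 1, 1 without control pool 3, 2 without mutant pool 1 and 0 without mutant pool 2, and 7 with DESeq2. Of 22 extracellular matrix genes, 10 were called higher, 0 lower and 12 not called, and 15 were higher when adjusted over the list alone. The median was 0.29, and camera called the list higher (adjusted p = 1.48e-09; adjusted p = 0.294 with an estimated correlation). Loxl2, encoding a lysyl oxidase, rose by 0.37 (SE 0.042), the laminin gene Lamb1 by 0.27 (SE 0.041), and the tenascin gene Tnc by 0.85 (SE 0.175). Called matrix members numbered 2 without control pool 1, 6 without control pool 3, 5 without mutant pool 2 and 5 without both pools that had almost no Xist counts.

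Of 13 pericyte and smooth muscle genes, 3 were called higher, 0 lower and 10 not called, and 3 were higher when adjusted over the list alone. Camera called the list higher (adjusted p = 0.00305; adjusted p = 0.400 with an estimated correlation), and the median was 0.07 while the mean was -0.23. The list call was lost without control pool 3 (camera adjusted p = 0.0852). The called members were the pericyte genes Cspg4 at 0.63 (SE 0.063), Abcc9 at 0.64 (SE 0.073) and Kcnj8 at 0.65 (SE 0.097), the last of these encoding a potassium channel subunit that pairs with the Abcc9 product. Rgs5, also a pericyte gene, at 0.02 (SE 0.086) and Notch3 at 0.19 (SE 0.125) were not called. The smooth muscle myosin gene Myh11 stood at 73.6 CPM in control pool 2 and at 6.54 CPM or less in the other pools. Without control pool 2, 5 members were called higher. Of 9 mesothelial genes, 0 were called by edgeR, also when adjusted over the list alone, while 4 had an unadjusted value under 0.05 and 2 were called by DESeq2 and 0 by limma voom. The mesothelial list was not called (median 0.22, camera adjusted p = 0.0555), but it was called higher with total-count scaling (0.0405), no filter on low counts (0.0493) and limma voom (0.0301). The replicate block also called the mesothelial list higher (camera adjusted p = 0.0164), with 3 members called. The mesothelial list was called higher without control pool 1 (camera adjusted p = 0.02), mutant pool 2 (0.0263) or mutant pool 3 (0.0141), and 1 member was called in the last of these fits.

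Pathway lists showed changes in single members more than shifts of the whole list. Of 20 Notch pathway genes, 4 were called higher, 2 lower and 14 not called, and 5 were higher and 3 lower when adjusted over the list alone. The list was not called (camera adjusted p = 0.18). The Notch effector genes Hey2 and Heyl rose by 0.74 (SE 0.1) and 0.69 (SE 0.11), the ligand gene Jag1 rose by 0.39 (SE 0.06), and the ligand gene Dll1 fell from 40.6 ± 1.38 to 27.6 ± 3.79 CPM. Of 17 Wnt targets and antagonists, 1 was called higher, 3 lower and 13 not called, and 3 were higher and 5 lower when adjusted over the list alone. Camera did not call the Wnt list (adjusted p = 0.266, lower), and its median was 0.01 while its mean was -0.15. Notum, encoding a secreted enzyme that inactivates Wnt proteins, fell from 17.2 ± 0.176 to 4.63 ± 0.953 CPM, a log2 fold change of -1.89 (SE 0.142, adjusted p = 0.00019 by edgeR). Sfrp1, encoding a secreted Wnt antagonist, rose by 0.68 (SE 0.094). Members of the Wnt list called lower numbered 1 without control pool 1 and 1 without mutant pool 2, and the call of the transcription factor gene Lef1 at -0.65 (SE 0.132) was lost in both cases (edgeR adjusted p = 0.0741 and 0.0758).

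Of 17 hypoxia and glycolysis genes, 2 were called higher, 1 lower and 14 not called, with the same numbers when adjusted over the list alone, and the list was not called (camera adjusted p = 0.457). Car9, encoding a carbonic anhydrase of the cell surface, rose from 17.3 ± 5.45 to 51.2 ± 1.56 CPM, whereas Ndrg1, another hypoxia-induced gene, fell from 64.5 ± 4.41 to 32.2 ± 2.63 CPM. The third called gene, the lactate dehydrogenase gene Ldha at 0.17 (SE 0.043), lost its edgeR call on leaving out any single pool, with adjusted p between 0.0734 without control pool 2 and 0.147 without mutant pool 1. Of 14 p53 targets and cell cycle inhibitors, 1 was called lower and 13 were not called, with the same number when adjusted over the list alone, and the list was not called (camera adjusted p = 0.722). That gene, Cdkn1a, encoding the inhibitor p21, changed by -0.35 (SE 0.065), and its edgeR call was lost without control pool 1 (adjusted p = 0.0604) or mutant pool 3 (0.0564). Of 26 cell cycle genes, 0 were called by edgeR, DESeq2 or limma voom, also when edgeR was adjusted over the list alone, and 1 had an unadjusted value under 0.05. Their log2 fold changes ran from -0.10 to 0.18 (camera adjusted p = 0.628). Of 12 interferon and inflammation genes, 2 were called higher and 10 not called, and 3 were higher when adjusted over the list alone. Camera called that list higher (adjusted p = 0.0355; adjusted p = 0.379 with an estimated correlation), and the call was lost without control pool 2 (0.0951), control pool 3 (0.108), mutant pool 1 (0.084) or mutant pool 2 (0.055), without both pools that had almost no Xist counts (0.167), with no filter on low counts (0.0902) and with limma voom (0.0636). The chemokine gene Cxcl12 rose by 0.62 (SE 0.049), and the interferon-induced gene Bst2 was called higher at 0.52 (SE 0.134), a call that edgeR made again without mutant pool 3 but not without any other single pool, with adjusted p up to 0.144 without mutant pool 2. Of 13 immediate early and heat shock genes, 0 were called by edgeR, also when adjusted over the list alone, while 3 had an unadjusted value under 0.05, 1 was called by DESeq2 and 0 by limma voom, and 1 was called by edgeR without mutant pool 3. That list was not called (camera adjusted p = 0.106), but it was called higher with no filter on low counts (0.0467), limma voom (0.0433) and fry (0.0391).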

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

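The fit without both libraries that had almost no Xist counts (control 3 and mutant 1) was chosen after the data had been seen, and the other alternatives were planned. No gene called in the comparison changed sign under any alternative run. The other scalings, filters and tests called between 1115 genes (limma voom) and 1304 genes (DESeq2, with 1059 of them shared with the 1167), and the median log2 fold change over all genes stayed between -0.026 and 0.003. Leaving out 1 library at a time gave between 629 and 1421 called genes, between 282 and 696 higher, between 343 and 725 lower, between 126 and 215 lower by at least 1 log2, and between 4 and 9 lists higher. These fits had fewer samples, and the fit without control 2 called more genes, not fewer. Control 2 held the most counts of some smooth muscle genes, with Myh11 at 73.6 CPM and Cnn1 at 9.81 CPM. The other libraries held at most 6.54 and 1.32 CPM of these genes, whereas the pericyte gene Rgs5 was alike in the control libraries. Whether this raised the number of calls was not tested. Without both libraries with almost no Xist counts, 665 genes were called, 315 higher and 350 lower, with 129 lower by at least 1 log2 and 4 lists higher. In that fit Hnf4a, Nkx6-1, Pdpn, Flt1, Col1a1, Onecut3, Cdkn1a, Ldha and Bst2 were among the named genes that lost their call, with edgeR adjusted p between 0.0582 for Onecut3 and 0.251 for Bst2. Camera with an estimated correlation called 0 lists higher and 0 lower, and fry, which does not compare a list with other genes, called 2 higher and 3 lower. By fry the matrix (adjusted p = 0.0349) and immediate early (0.0391) lists were higher. The endocrine progenitor (0.0173), hormone (0.0136) and hepatocyte (0.0136) lists were lower by fry. All other lists called with the preset correlation lost their call with fry, among them the acinar (0.177), erythroid (0.0829) and neuron (0.0668) lists. Signs turned only for results that were not called. Flt4 was at -0.017 with total-count scaling, at -0.134 without both libraries with almost no Xist counts, and between -0.076 and 0.096 with 1 library left out. Ptf1a ranged between -0.03 and 0.243 with 1 library left out. The cell cycle list turned direction without control 2, without mutant 1 and without both libraries with almost no Xist counts. Its unadjusted probability in limma's camera was between 0.347 and 0.784 with 1 library left out and 0.823 without both libraries, where the lymphatic list also turned, at 0.476. The replicate number as a block gave 1138 called genes, 995 of them among the 1167. Deviations from the group means correlated by 0.138, 0.101 and -0.05 for pools with equal numbers, and control 2 and control 3 correlated better with a mutant pool of another number, so the numbers were not taken as pairs. Named genes that lost a call under a scaling, filter or test were Ldha and Bst2 (total-count scaling, limma voom), Onecut3 and Ins2 (limma voom), Ldha (CPM filter, replicate block), and Prss1 and Prss3 (robust estimation). Calls were gained for Sox9 and Lyve1 with DESeq2 and for Sox9 and Pecam1 with the replicate block. Total-count scaling, no filter, limma voom and the replicate block each called 9 lists higher in place of 7. All 4 gained the mesothelial and macrophage lists, no filter and limma voom also gained the immediate early list and lost the interferon list, and the replicate block called 3 mesothelial and 3 macrophage genes, 4 blood endothelial genes in place of 1, 2 gut genes in place of 1 and 1 hypoxia gene in place of 2. The depth limits genes below about 1 CPM, and the sample size limits changes of 0.5 log2 or less.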

Other observations

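The genes outside the lists described first were chosen after their values had been seen. Of the tests, the count of splits of the libraries and the test of genes near Prox1 were planned, and the tests for swapped libraries, transcribed mutant alleles, liver tissue, epithelial share, endocrine share, trypsinogen reads and acinar share were chosen after the results had been seen.

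Some peptide hormone genes that are also expressed in the gut were higher and others lower in mutants, and Pyy and Ghrl of the hormone list were among the lower ones. Cck, encoding cholecystokinin, rose from 12.6 ± 1.84 to 51.8 ± 4.81 CPM (SD, n = 3), a log2 fold change of 2.04 (SE 0.11), and Gip, encoding the incretin of duodenal K cells, rose by 2.63 (SE 0.189), from 2.25 ± 0.543 to 13.9 ± 2.1 CPM. Gast, encoding gastrin, changed by -1.99 (SE 0.187) and Sct, encoding secretin, by -1.59 (SE 0.178), both from below 10 CPM in controls. The edgeR calls of Cck, Gip, Gast and Sct each had an adjusted p of 0.00117 or less. All 3 mutant pools lay on the same side of all 3 control pools, as for every called gene. Aldh1b1, a retinaldehyde and acetaldehyde dehydrogenase gene of pancreatic progenitors, changed by -1.75 (SE 0.137), while Aldh1a1, another aldehyde dehydrogenase gene, rose by 2.81 (SE 0.191). Abcc8, encoding the sulfonylurea receptor of islet cells, changed by -1.04 (SE 0.061) and the nucleoside transporter gene Slc28a3 by -1.95 (SE 0.105).

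Several further genes differed by many times their standard error. Enpp2, encoding autotaxin, the enzyme that makes lysophosphatidic acid, rose from 76.2 ± 1.98 to 346.2 ± 11.9 CPM, a log2 fold change of 2.18 (SE 0.044, adjusted p = 5.26e-08 by edgeR). Ntn1, encoding netrin 1, rose by 1.47 (SE 0.058), and the intermediate filament gene Nes rose by 1.33 (SE 0.06). Cxcr4, encoding the receptor for the chemokine product of Cxcl12, rose by 1.00 (SE 0.071). The hedgehog target Gli1 rose by 1.72 (SE 0.296), while the hedgehog targets Ptch1 at -0.13 (SE 0.115) and Hhip at -0.13 (SE 0.124) were not called. Prtn3 and Elane, which encode proteases of neutrophil granules, rose by 2.01 (SE 0.222) and 3.31 (SE 0.381), whereas Alas2, the haem synthesis gene of red cells, was not called at -0.05 (SE 0.178).

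For the 1167 genes changed between mutant and control, 1 of the 10 splits of the 6 libraries, the real one, gave as many changed genes, and the highest of the other splits gave 0. With 10 splits the share cannot fall under 0.05.

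Prox1 counts in the mutant libraries stayed close to the controls. A swap of single libraries between the groups would leave libraries that correlate better with the other group than with their own, and 0 of the 6 libraries did, which argues against it. Transcription of the mutant alleles across the exons that were counted may account for the counts, since 61.8% of the annotated exon length is 3′ untranslated region. A count per gene cannot show which exons the reads came from, so this stays open. A biological cause was not tested.

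The hepatocyte list had the lowest median log2 fold change of the 23 lists, at -0.97. Liver tissue in the control dissections is a possible source. However, 9 genes abundant in liver, among them Alb and the fibrinogen and apolipoprotein genes, summed to 15.1 CPM in controls. The other 7 called members fell together by 482.3 CPM, which argues against liver as the main source. Afp and Ttr, hepatocyte markers too, were counted among those 7, so the contrast depends on how the list was divided. A smaller share of epithelium in mutants would lower the hepatocyte and epithelial junction lists by about the same median. The hepatocyte median lay -0.81 log2 from that of the junction list (two-sided permutation of genes, p = 2e-05). A smaller share of endocrine cells cannot be told apart from a change within cells. The hepatocyte median lay -0.25 log2 from that of the hormone and granule list (two-sided permutation of genes, p = 0.209). Both permutations shuffled genes as if independent, so the p-values measure spread among genes, not between pools. The hepatocyte list fell by more than the junction list in these pools, but no test over pools decided either explanation. The effect of genotype on these genes within the pancreatic epithelium stays open as a hypothesis.

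Ctrl, Gp2, Rnase1 and other acinar genes rose, while the abundant enzyme genes Cpa1, Pnliprp1 and Ctrb1 were not called. Their log2 fold changes were 0.46 (SE 0.191), 0.42 (SE 0.318) and 0.13 (SE 0.353). They varied widely between control pools, with Pnliprp1 between 546.8 and 1675 CPM and Ctrb1 between 339.4 and 1030 CPM. The missing calls therefore do not show that these genes were unchanged. Exchange of reads among the near-identical trypsinogen genes may add to the values of Prss1 and Prss2, but 5 of the 7 genes of the list called higher are not trypsinogens, which argues against it as the whole cause. A larger share of acinar cells was tested on the premise that it would raise every member alike. Of the 26 tested members, 19 had an upper 95% bound below the smallest called rise of 1.65 log2. That cut-off came from the 7 members called higher in the same data, so the count largely restates the calls and cannot decide the question. Bhlha15 at -0.80 (SE 0.19) and Cela3b at -1.29 (SE 0.319) were called lower, so the members did not all rise alike. A share acting unequally on the members was not tested. An effect of genotype on a subset of acinar genes is a hypothesis that these data raised and cannot test again.

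Genes within 10 Mb of Prox1, where flanking DNA of the targeted alleles would lie, were called at a rate of 12.4% (11 of 89), against 8% (1148 of 14426) elsewhere. The odds ratio was 1.63 (95% interval 0.78 to 3.09, two-sided Fisher exact p = 0.164), an interval that leaves open both no excess and a 2-fold excess.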
